A study of Homo sapiens with 9 samples.

How the data were processed

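RNA-seq was carried out on Z138, an established mantle cell lymphoma line, in 3 states: wild type, SOX11 knockout and SOX11 rescue, with 3 libraries per group and 9 in all. Per the labels' protocols, the RNA was polyadenylated RNA, and libraries were made either with a TruSeq RNA kit or with a stranded total RNA kit with ribosomal depletion and read on an Illumina NextSeq as paired or single ends. Which library had which kit or layout is not given in the sources used here, so genes with an antisense partner are uncertain. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.40, kallisto 0.46.1, R 4.3.2 and DESeq2 1.24.0 were used with the genome build GRCh38.p13. The labels do not say whether replicates were separate cultures or whether the knockout and the rescue are single clones. The p-values then measure only the spread between these libraries, and differences between clones are not separated from those due to SOX11.

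The deposited table holds log2 values for 16586 genes in the 9 libraries, 1 of them without a symbol. Its name calls them log CPM, but the values are on a variance-stabilized log2 scale: all 9 libraries share the lowest value 8.5985, and 2 to the power of the values sums to between 44600000 and 45700000 per library. The closed form of this transform was inverted, with 2 to the lowest value (388) as its constant, to give normalized counts. Low values then fell at whole multiples of a step of 0.856 to 1.13 normalized counts per library, the worth of 1 read. Among genes with a single annotated transcript, between 90.1% and 99.2% of low values lay within 0.05 of a step of a whole multiple, against 10.0% by chance. Over all genes this was 51.4% to 55.1%, since kallisto divides reads between transcripts. Dividing the total normalized count by the step put the depth at 30800000 to 40900000 reads per library. This depth is an estimate, and floors cover counting error only. CPM was taken from each library's share of normalized counts. The tests had been planned on log2 CPM. Because the file held variance-stabilized values, they were run on those values as deposited, and the planned filter was applied to the recovered CPM. Differences on this scale understate the change of low genes, so folds are given from mean normalized counts.

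Genes with a CPM of at least 1 in at least 3 libraries were tested, which kept 11542 genes and left out 5044. limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with a mean per group and a trended prior variance, and p-values were adjusted by the method of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. SOX11 was also compared by a two-sided exact permutation test. Of the 33 gene lists fixed before the data were examined, 30 had at least 5 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. A gene was called reversed when it passed the threshold in the knockout against wild type and, in the opposite direction, in the rescue against the knockout. Gene symbols are those of the file. Positions come from GENCODE release 29 on GRCh38, which matched 16461 of the genes by identifier.

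The genes named were set by a rule: SOX11 first, then for each comparison the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, with a mean log2 CPM of at least 1 in the higher group. Pseudogenes, clone names and genes without a symbol were passed over. The 8 reversed genes with the largest knockout change in each direction were added, and for each list up to 4 members with the smallest adjusted p and every member of the SOX11-linked list. Genes outside the rule are said to be so, or are the members of a family or test named with them.

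The labels give each library a batch, which equals its replicate number and is crossed with the groups, so the numbers pair the libraries. Deviations from the group means of same-numbered libraries correlated at 0.187 to 0.51 across genes, and 9 of the 9 libraries correlated best with a library of their own number. The fit without the replicate block was the planned main fit. The alternatives were the replicate block, no filter, a stricter filter (log2 CPM of at least 2 in at least 3 libraries), log2(CPM + 1), median centring, quantile normalization, a constant or a robust prior variance, a fit of only the groups compared, and leaving out each library or each batch. The fit was tested on simulated counts for the 11542 genes with the knockout against wild type layout, 200 of them changed. It recovered 23.3% of the genes changed 1.25-fold, 51.7% at 1.5-fold, 81.5% at 2-fold and 100% at 4-fold, and 5.1% of its calls were genes that had not been changed. The simulated libraries had no batch effect, and far fewer genes were changed than the 1470 called in the data. These rates therefore need not hold for the data. Figures were drawn with matplotlib 3.10.9.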

Results

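The data were 9 RNA-seq libraries of Z138, a cell line from mantle cell lymphoma, a B cell cancer. The 3 groups were wild-type cells, cells with SOX11 knocked out, and knockout cells in which SOX11 had been returned, called the rescue, with 3 libraries each. SOX11 is a transcription factor of the nervous system that most mantle cell lymphomas express. Estimated depth was 30800000 to 40900000 reads per library. Libraries of one group correlated at 0.995 to 0.998 across genes. The first principal component held 48.2% of the variance and set the knockout apart from both other groups. The second held 17.3% and set batch 2 apart, with positive values in its 3 libraries and negative values in the other 6. Normalized counts below are means ± SD with n = 3 libraries per group, and adjusted p-values are from limma.

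SOX11 itself (ENSG00000176887.7, chromosome 2, 5692667 to 5701385, plus strand) was measured first, as a check of the labels. Its normalized count was 3549 ± 474 in wild type, 1033 ± 262 in the knockout and 13127 ± 627 in the rescue. The knockout thus kept 29.1% of the wild-type transcript level, and the rescue held 369.8% of it. On the deposited log2 scale the knockout fell by 1.32 (SE 0.107, adjusted p = 1.46e-05) and the rescue lay 3.03 above the knockout (adjusted p = 2.80e-08) and 1.70 above wild type (adjusted p = 6.31e-06). No group overlapped another, and the exact two-sided permutation p was 0.1 for each pair, the smallest that 3 against 3 allows. Transcript counts over the whole gene do not show whether the remaining transcript is edited.

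**Figure D1:**
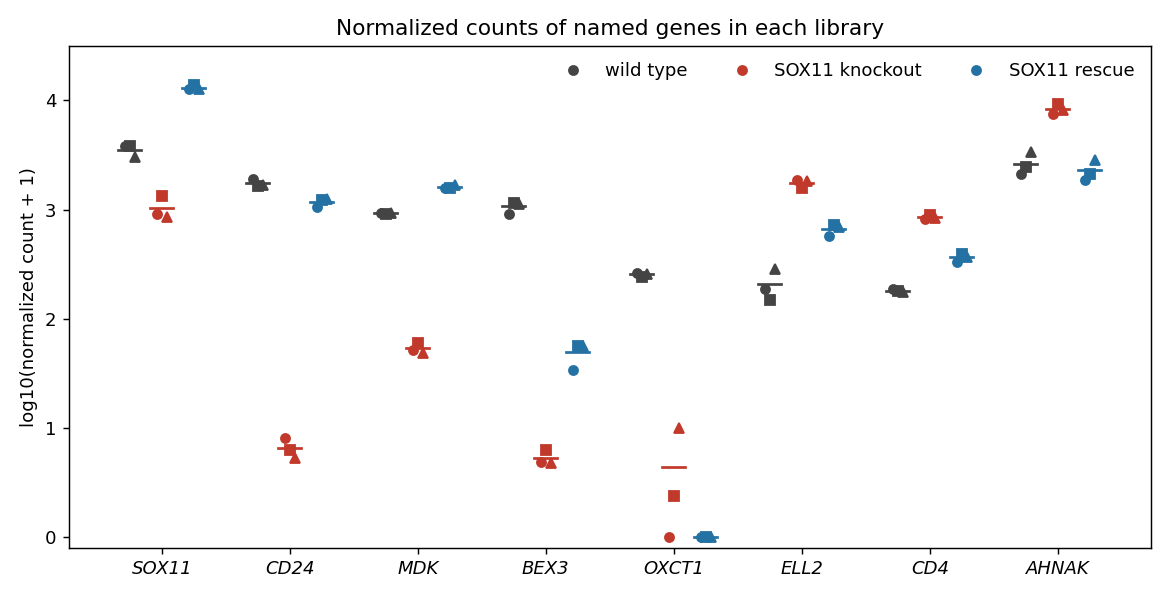
Normalized counts of 8 named genes in each library, as log10(normalized count + 1). Circles, squares and triangles are replicates 1, 2 and 3, and lines are group means; SOX11 averages 3549, 1033 and 13127 in wild type, knockout and rescue, and OXCT1 is at 0 in the 3 rescue libraries.

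The knockout was compared with wild type to ask which transcripts differ when SOX11 is lost. CD24, a surface glycoprotein of B cells and their precursors, fell from 1741 ± 147 to 5.51 ± 1.41 normalized counts, 316-fold (adjusted p = 2.46e-09). MDK, the growth factor midkine, fell 17.7-fold from 925 ± 8.67 to 52.3 ± 6.28, and BEX3 fell 247-fold from 1067 ± 129.8 to 4.31 ± 0.855. In the other direction ELL2, an elongation factor that acts in plasma cells, rose 8.51-fold from 207 ± 71 to 1760.2 ± 158 (adjusted p = 7.67e-07). CD4 rose 4.71-fold to 846 ± 37.5. CD24 has near-identical processed copies in the genome, so its level is less certain than the others.

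Other large falls were the formin FMNL2 (13.1-fold), CRACD (25.2-fold), and the exchange factors FARP1 (5.09-fold) and PLEKHG4B (5.12-fold). The kinase HIPK2 fell 7.97-fold, MLLT11 4.82-fold, the protease inhibitor SPINT2 5.23-fold and SCCPDH 3.87-fold, with adjusted p-values of 5.65e-05 or below across these genes. Other large rises were S1PR4, a sphingosine-1-phosphate receptor of lymphocytes (6.92-fold), ACY3 (5.2-fold), the transporter ABCC4 (4.53-fold), the integrin chain ITGB7 (3.38-fold), AHNAK (3.17-fold), CORO2B (2.65-fold), the cytidine deaminases APOBEC3G (2.55-fold) and APOBEC3C (2.25-fold), STS (2.08-fold) and PEG10 (2-fold, from 14137 to 28249). Reads of the APOBEC3 paralogs can be divided between them.

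Of 16 tested genes that earlier work ties to SOX11 in mantle cell lymphoma, 7 fell and none rose (adjusted over the list alone, 8 fell and 1 rose). Besides CD24 these were DBN1, an actin-binding protein (2.19-fold), the growth factor PDGFA (2.22-fold), STMN1 (1.32-fold), the RNA-binding protein MSI2 (1.32-fold), SETMAR (1.28-fold) and the chemokine receptor CXCR4 (1.21-fold). SETMAR lost its call when only the 2 groups compared were fitted, and without wild-type replicate 2, any single knockout replicate or any 1 batch, and CXCR4 when any 1 batch was left out. PAX5, the B cell transcription factor, averaged 10832 ± 3013 in wild type and 7474 ± 1867 in the knockout and did not pass (adjusted p = 0.12), but did with the replicate block (adjusted p = 1.10e-04) and without knockout replicate 2. BCL6 and PRDM1 were also not called in the main fit. The members were not divided by the direction that earlier work gives them, so these counts do not measure agreement with it. The list was lower by camera (adjusted p = 2.28e-04; adjusted p = 0.106 with an estimated correlation).

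Among the genes of MHC class II presentation, 6 of 14 tested members rose and none fell (adjusted over the list alone, 9 rose). They included the invariant chain CD74 (1.43-fold), HLA-DPA1 (1.56-fold) and the regulators RFX5 (1.27-fold) and CIITA (1.31-fold), and camera gave adjusted p = 2.16e-04 (adjusted p = 0.303 with an estimated correlation). Of 12 MHC class I presentation genes 4 rose, among them TAP1 (1.5-fold) and ERAP2 (1.18-fold), and 1 fell, ERAP1, which is outside the naming rule (adjusted over the list alone, 5 higher and 1 lower; adjusted p = 0.308 with an estimated correlation). That list call was lost without wild-type replicate 1 or 3, knockout replicate 2 or 3, or batch 1 or 3. Of 17 plasma cell genes 3 rose: ELL2, FKBP11 (1.5-fold) and JCHAIN (1.34-fold). IRF4, a regulator of the same programme, fell 1.27-fold (plasma cell list, adjusted over the list alone, 7 higher and 3 lower; adjusted p = 0.267 with an estimated correlation). Among 17 Wnt and stem cell genes 7 fell and 1 rose. WNT16 fell 2.45-fold, FZD6 5.44-fold and the Wnt target AXIN2 2.26-fold, while NOTCH2 rose 1.29-fold (adjusted over the list alone, 1 higher and 8 lower; adjusted p = 0.267 with an estimated correlation). Of 5 tested neuronal genes 3 fell: MAP2 (2.83-fold), TUBB2B (1.45-fold) and CRMP1, which went from 96.9 ± 10.9 to 0 in the 3 knockout libraries, at least 31.6-fold lower against a floor of 3 reads per library. The neuronal list was lower by camera (adjusted over the list alone, 0 higher and 3 lower; adjusted p = 0.267 with an estimated correlation), a call that was lost without the filter. Of 23 immediate early and heat shock genes 7 fell and 2 rose, with NR4A1 3.17-fold and EGR2 2.97-fold lower (adjusted over the list alone, 2 higher and 7 lower; adjusted p = 0.679 with an estimated correlation), a list call lost without wild-type replicate 1 or 3, knockout replicate 2, or batch 1 or 3.

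Of 9 tested T and NK cell markers 4 rose, CD4, PRF1 (3.27-fold), CD3E (2.25-fold) and NKG7 (from 12.6 ± 3.87 to 43 ± 3.14), and the list was higher (adjusted over the list alone, 5 higher and 0 lower; adjusted p = 0.141 with an estimated correlation), though not without the filter. Measures of library quality also moved. Replication-dependent histone genes were lower by camera (adjusted p = 0.00761; adjusted p = 0.68 with an estimated correlation), with H1-2 4.77-fold lower, and so were cytosolic ribosomal protein genes (adjusted p = 0.729 with an estimated correlation), with 1 of 34 members called (adjusted over the list alone, 0 higher and 0 lower). The histone call was lost without wild-type replicate 3 or knockout replicate 2, and the ribosomal call without wild-type replicate 2 or knockout replicate 1 or 2, and both without batch 2. Mitochondrially encoded genes did not pass (camera adjusted p = 0.0684; adjusted p = 0.729 with an estimated correlation) but did with the replicate block at the preset correlation (camera adjusted p = 0.0293).

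In all, 1470 of 11542 genes were called, 619 higher and 851 lower in the knockout, and the 1470 changed in one direction within each of the 3 batches. Since genes were called from these same libraries, such agreement is close to given and is no separate test, here and in the other comparisons. By mean normalized count, 108 of the higher and 337 of the lower genes differed at least 2-fold. With the replicate block 2481 genes were called (1172 higher, 1309 lower), and the 1470 were among them. The groups did not overlap for 29.5% of genes, against 10% by chance. Camera moved 13 of the 30 lists, including oxidative phosphorylation (3 of 28 members higher; adjusted over the list alone, 6 higher and 1 lower; adjusted p = 0.68 with an estimated correlation), G2 and mitosis (1 of 26 higher; adjusted p = 0.729 with an estimated correlation) and MYC and ribosome biogenesis (1 of 26 higher; adjusted p = 0.729 with an estimated correlation). With an estimated correlation camera moved 0 lists, and 5 had an unadjusted p under 0.05. Of the lists moved by camera, fry passed the SOX11-linked (fry adjusted p = 1.27e-05), T and NK cell, neuronal, plasma cell, Wnt and both MHC lists. It did not pass oxidative phosphorylation (fry adjusted p = 0.114), G2 and mitosis, MYC and ribosome biogenesis, immediate early and heat shock, histones or ribosomal proteins. Without knockout replicate 2, 8 lists moved. The call count was 938 without knockout replicate 1, 575 without batch 1 and 574 without batch 3.

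The rescue was compared with the knockout to ask which changes go back when SOX11 is returned. CD24 rose 213-fold to 1173 ± 106 normalized counts (adjusted p = 8.32e-09), MDK 30.7-fold to 1605 ± 57.9 and CRACD 45.6-fold to 1063 ± 127. TMEFF1, a transmembrane protein of the nervous system, rose from 10.1 ± 10.6 to 722 ± 102 and ASAP2 from 9.13 ± 8.16 to 601 ± 114. AHNAK fell 3.66-fold, ITGB7 3.68-fold and ACY3 3.33-fold.

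Further rises were FMNL2 (17.7-fold), MLLT11 (8.47-fold), HIPK2 (5.99-fold), the alpha-tubulin TUBA1A (3.39-fold, to 23087 ± 2083), the Notch regulator DTX1 (3.04-fold) and MARCKSL1 (2.94-fold). Further falls were the cell cycle kinase CDK6 (5.02-fold), SYNPO (2.81-fold), the cytokine IL10 (2.77-fold), ELL2 (2.67-fold), CPT1A, which brings fatty acids into mitochondria (2.66-fold), the glucocorticoid receptor NR3C1 (2.56-fold), TFEC (2.26-fold), PEG10 (2.22-fold) and the ion channel PIEZO1 (2.06-fold).

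Of the 16 SOX11-linked genes 10 rose and 1 fell. DBN1 rose 2.52-fold, PDGFA 2-fold, STMN1 1.68-fold and PAX5 1.65-fold, and TEAD2 went from 1.11 ± 0.467 to 78 ± 9.65. BTK fell 1.23-fold (adjusted over the list alone, 10 higher and 3 lower; adjusted p = 0.103 with an estimated correlation). PAX5, TEAD2 and BTK had not been called in the knockout against wild type in the main fit, so they are not among the reversed genes. TEAD2 was instead called above wild type in the rescue. PAX5 lost its call without knockout replicate 1 or 3 or rescue replicate 2. Of 14 MHC class II presentation genes 10 fell and none rose, with CIITA 1.71-fold, HLA-DPB1 1.99-fold and CD74 1.53-fold lower (adjusted over the list alone, 0 higher and 11 lower; camera adjusted p = 2.14e-05; adjusted p = 0.287 with an estimated correlation). Of 12 MHC class I genes 6 fell, with TAP1 1.7-fold lower (adjusted over the list alone, 0 higher and 6 lower; adjusted p = 0.233 with an estimated correlation). Oxidative phosphorylation genes fell in 16 of 28 cases by small amounts, such as NDUFV1 (1.34-fold) and CYCS (1.36-fold; adjusted over the list alone, 0 higher and 17 lower; list adjusted p = 0.549 with an estimated correlation). Of 26 genes of MYC and ribosome biogenesis 8 fell, including MYC itself (1.44-fold; adjusted over the list alone, 0 higher and 9 lower; list adjusted p = 0.616 with an estimated correlation). Of 17 plasma cell genes 8 fell and IRF4 rose, with FKBP11 1.88-fold and XBP1 1.52-fold lower (adjusted over the list alone, 2 higher and 10 lower; adjusted p = 0.233 with an estimated correlation). Of 25 genes of the unfolded protein and integrated stress response 10 fell and 2 rose, with HSP90B1 1.39-fold lower and VLDLR 1.55-fold higher (adjusted over the list alone, 2 higher and 11 lower; adjusted p = 0.616 with an estimated correlation). Of 23 p53 targets 12 fell and 2 rose, with FDXR 1.97-fold lower and BTG2 2.07-fold higher (adjusted over the list alone, 3 higher and 15 lower; adjusted p = 0.233 with an estimated correlation). Some lists held called members without moving as a set: of 24 B cell receptor signalling genes 8 fell and 3 rose (adjusted over the list alone, 3 higher and 9 lower), and of 16 NF-kB targets 6 rose (adjusted over the list alone, 6 higher and 1 lower). Among the 10 tested immunoglobulin genes JCHAIN, IGLC1 and IGLL5 fell while IGLC2 and IGLC3 rose (adjusted over the list alone, 3 higher and 4 lower), and these near-identical genes share reads.

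The rescue reversed 1120 of the 1470 genes called in the knockout: 643 of the 851 that had been lower (75.6%) and 477 of the 619 that had been higher (77.1%). SOX11 is 1 of them. Independent lists of these sizes would share 97.8 and 66 genes. Simulated unchanged groups that share the knockout libraries gave 0 in each of 100 simulations. Groups with no changed gene yield almost no calls, so this 0 says little about the excess. Across genes, the covariance of the 2 sets of changes was -0.0327 against a simulated -0.0027 (correlation -0.80 against -0.50). The simulated covariance already includes the sharing of the knockout libraries, as far as noise is independent between genes. Simulations with every gene of the rescue at its wild-type mean gave a mean correlation of -0.93. The knockout libraries were too few to be divided, so part of the excess of the counts over independent lists may come from sharing them. Between the rescue and the knockout 2556 genes were called, 1326 higher and 1230 lower (1209 and 1393 with median centring), and 2555 of them moved in one direction within the 3 batches. By mean normalized count 429 rose and 107 fell at least 2-fold. Of the 2556, 1425 had not been called in the knockout. With the replicate block 1875 of 2481 genes were reversed. Camera moved 8 lists, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. By fry these 8 passed except the unfolded protein and integrated stress response (fry adjusted p = 0.0564). The reversed count was 714 without knockout replicate 1, 424 without batch 1 and 400 without batch 3, and the rescue against knockout count was 1167 and 993 without those batches.

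**Figure D2:**
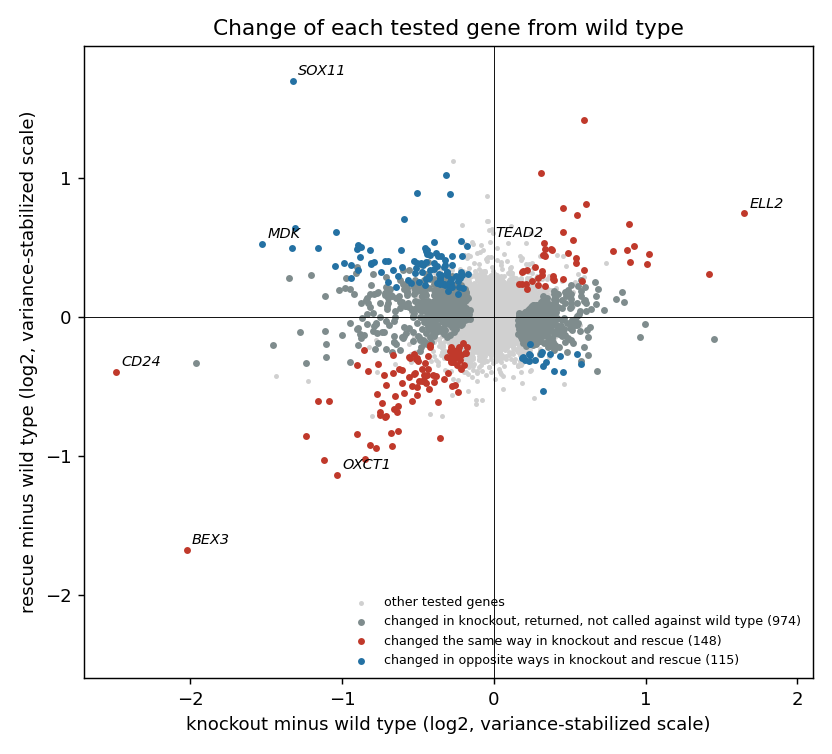
Change of each of the 11542 tested genes from wild type in the knockout (horizontal) and the rescue (vertical), as differences of mean variance-stabilized log2 values. Grey points mark 974 reversed genes not called against wild type, red points the 148 genes changed the same way in both, and blue points the 115 changed in opposite ways, SOX11 among them.

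The rescue was compared with wild type to ask what still differs. ABLIM1, an actin-binding protein, was 5.5-fold higher in the rescue (329 ± 45.3 and 1813 ± 78.5 normalized counts, adjusted p = 2.91e-07), the actin-bundling protein FSCN1 4.42-fold and the RNA-binding protein PCBP4 7.05-fold. BEX3 remained 22.2-fold lower at 48 ± 13 (adjusted p = 1.98e-07). OXCT1, an enzyme of ketone body use, had 253 ± 11.9 normalized counts in wild type, 3.4 ± 4.76 in the knockout and 0 in the 3 rescue libraries, at least 82.8-fold lower against a floor of 3 reads per library. CRMP1 was also at 0 in the 3 rescue libraries.

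Other named genes higher in the rescue were LGALS9 (4.01-fold), GMFG (3.7-fold), SYNPO2L (2.95-fold), GNG4 (2.93-fold), the tetraspanin CD9 (2.68-fold), the endothelial receptor TIE1 (2.33-fold), ELL2 (3.19-fold) and perforin, PRF1 (4.41-fold). Other named lower genes were TCEA3 (10.3-fold), SIRPA (5.81-fold), NRSN2 (4.46-fold), the histones H1-2 (4.08-fold) and H2BC12 (4-fold), LHFPL6 (3.97-fold), RPP25 (3.43-fold), WNT16 (3.03-fold), SCCPDH (2.4-fold) and BEND4 (2.37-fold). Histone paralogs share reads, and their transcripts mostly lack poly(A) tails. SYNPO2L, H1-2 and H2BC12 lost their calls without batch 3.

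Of 23 p53 targets 10 were lower in the rescue than in wild type and none higher (adjusted over the list alone, 16 lower). PHLDA3 was 2.63-fold lower, CDKN1A, the cell cycle inhibitor p21, 1.58-fold (from 7826 ± 652 to 4939 ± 766), BBC3 1.61-fold and ZMAT3 1.44-fold. The list was lower by camera (adjusted p = 8.68e-13) and stayed so with an estimated correlation (adjusted p = 0.0288). Of 9 T and NK cell markers 4 were higher: PRF1, LCK (2.11-fold), CD4 (2.02-fold) and CD3E (2.16-fold), adjusted over the list alone, 5 higher and 0 lower. That list also passed with an estimated correlation (adjusted p = 0.0288). Of the 16 SOX11-linked genes 3 were higher, among them TEAD2 and STMN1 (1.27-fold), and 2 lower, CD24 (1.48-fold) and the cyclin CCND1 (1.19-fold), and the list did not move (adjusted over the list alone, 4 higher and 3 lower; camera adjusted p = 0.573). The CCND1 call was lost when only the 2 groups compared were fitted, and without wild-type replicate 1 or 2, any single rescue replicate or any 1 batch. STMN1 lost its call when any 1 batch was left out and CD24 without batch 1 or 3. Mitochondrially encoded genes were higher as a list (camera adjusted p = 7.01e-04; adjusted p = 0.558 with an estimated correlation) with 0 of 13 members called by limma (adjusted over the list alone, 0 higher and 0 lower), and not without wild-type replicate 1 or rescue replicate 3. Replication-dependent histones (2 of 16 members lower; adjusted over the list alone, 0 higher and 3 lower; adjusted p = 0.558 with an estimated correlation) and cytosolic ribosomal proteins (0 of 34 called by limma; adjusted p = 0.56 with an estimated correlation) were lower as lists, the ribosomal one not without wild-type replicate 2 or batch 2.

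Of the 1470 genes called in the knockout, 148 differed from wild type in the same direction in the rescue (102 lower, 46 higher). Of these, 117 had not been reversed, among them OXCT1, CRMP1, WNT16 and H1-2, which were lower, and APOBEC3G, which was higher. The other 31 were reversed and still differed from wild type, such as BEX3 and SCCPDH on the lower side and ELL2, CD4, S1PR4 and APOBEC3C on the higher side. Independent lists would share 15.1 lower and 14.2 higher genes. Simulated unchanged groups that share the wild-type libraries gave at most 0 and 1, which says little, since such groups yield almost no calls. Another 115 genes lay beyond wild type, 96 that were lower in the knockout and higher in the rescue, such as MDK (1.73-fold above wild type), MLLT11 (1.76-fold) and PCBP4, and 19 the other way round. Independent lists would give 19.5 and 11. The 115 were 71 without wild-type replicate 3, 65 without rescue replicate 2, 56 without rescue replicate 3, 28, 61 and 12 without batches 1, 2 and 3, and 258 with the replicate block. The 148 were 90 without rescue replicate 3, 60, 96 and 55 without those batches, and 249 with the block. The covariance of the 2 sets of changes was 0.002 against a simulated 0.0027, and part of any overlap may come from sharing the wild-type libraries, which were too few to be divided.

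In all, 470 genes were called between the rescue and wild type, 265 higher and 205 lower (51 and 60 without batch 3), and the 470 moved in one direction within the 3 batches. With the replicate block 930 were called (493 higher, 437 lower), the 470 among them. Camera moved 12 lists, 7 without batch 2, and 2 with an estimated correlation. Beyond the lists given above, oxidative phosphorylation (camera adjusted p = 3.01e-05), MYC and ribosome biogenesis (camera adjusted p = 1.92e-04) and MHC class II presentation (camera adjusted p = 0.0316) were below wild type. So were the stress response, S phase, and immediate early and heat shock lists, while G2 and mitosis was higher (camera adjusted p = 0.0218). None of these passed with an estimated correlation. Of the 12 lists, only the p53 targets (fry adjusted p = 5.86e-04) and the T and NK cell markers (fry adjusted p = 9.18e-05) passed by fry. The call count was 251 without rescue replicate 2, 230 without rescue replicate 3, and 146, 249 and 111 without batches 1, 2 and 3.

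**Figure D3:**
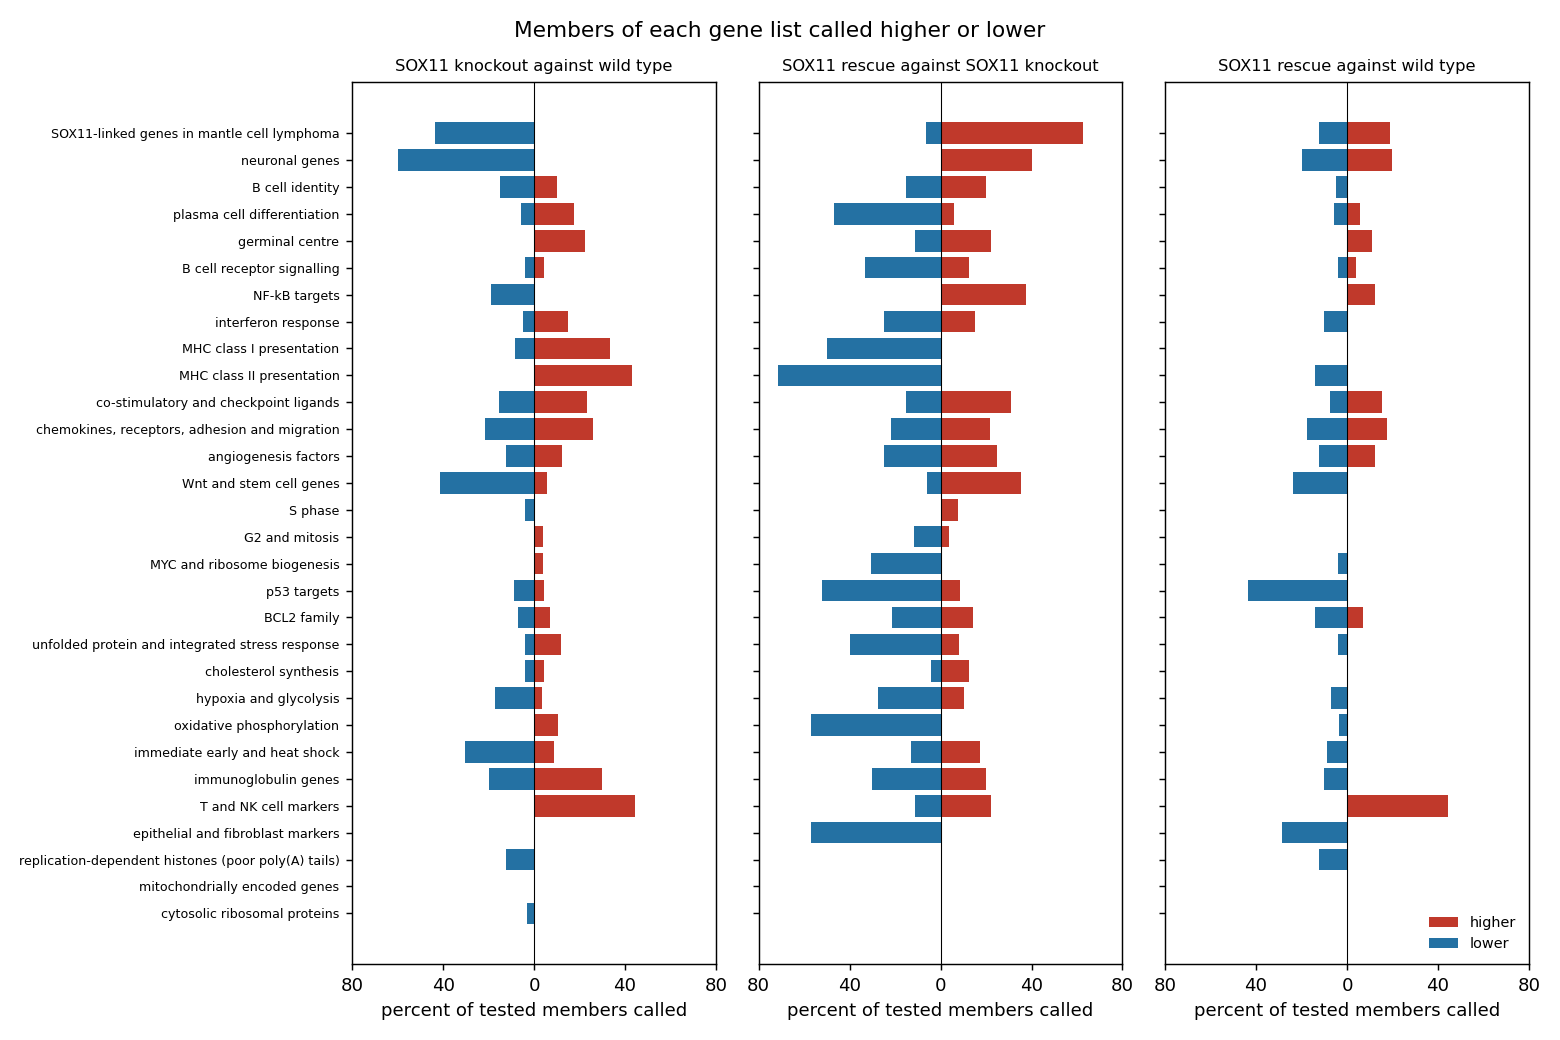
Percent of tested members called higher (red, right) or lower (blue, left) for each of the 30 lists in the 3 comparisons. Of the MHC class II presentation genes 6 of 14 are higher in the knockout and 10 of 14 lower in the rescue against the knockout.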

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

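Of the genes and lists followed through the alternatives, none that was called in the main fit or an alternative changed direction between them. The balance of higher and lower calls did turn: in the rescue against the knockout, from 1326 and 1230 to 1130 and 1184 with the stricter filter, 1209 and 1393 with median centring and 1236 and 1340 with quantile normalization, and in the rescue against wild type, from 265 and 205 to 185 and 189 without wild-type replicate 3 and 51 and 60 without batch 3. With the replicate block 2481 genes were called in the knockout against wild type and 930 in the rescue against wild type, 1875 were reversed, 249 changed in the same way in knockout and rescue, and 258 lay beyond wild type. Among the calls it added were BTK and PAX5 in the first comparison, CCND1 and CD70 in the second, CD70 and PAX5 in the third, and 2 lists in the first (stress response and mitochondrially encoded genes). The block changed no other list call and ended no call of a named gene. In the knockout against wild type 8 lists moved under the stricter filter and 8 under quantile normalization. With an estimated inter-gene correlation 0, 0 and 2 lists moved in the 3 comparisons in the order of the report. The count of genes beyond wild type was added after the data were seen.

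Leaving out each library or each batch in turn, genes called ranged from 574 to 1395 in the knockout against wild type, from 993 to 2156 in the rescue against the knockout and from 111 to 374 in the rescue against wild type. Reversed genes ranged from 400 to 1102, genes changed the same way in both from 55 to 131, and genes beyond wild type from 12 to 91. Lists moved ranged from 8 to 14, from 8 to 9 and from 7 to 15. The SOX11 difference ranged from -1.45 to -1.23, from 2.95 to 3.15 and from 1.60 to 1.76 and passed throughout. Fewer libraries leave less power, and where 1 batch was left out each group had 2 libraries. Over named genes these fits ended 46 of the calls tested and added 3. No other scaling moved the median of all genes by over 0.1 or the share of higher calls by over 10 percentage points.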

Other observations

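Of 6 tested APOBEC3 genes, cytidine deaminases that lie side by side on chromosome 22 between 38982347 and 39104067, 5 rose in the knockout. This family was picked after its values were seen, as 1 of 2 families looked at in this way. APOBEC3D rose 3.38-fold from 86.3 ± 7.93 to 291 ± 15.4 normalized counts, APOBEC3H 3.10-fold, APOBEC3G 2.55-fold, APOBEC3F 2.35-fold and APOBEC3C 2.25-fold, while APOBEC3B held 760.3 ± 97.4 and 751 ± 76.4 (limma adjusted p = 0.959). In the rescue 5 were above wild type, with APOBEC3B among them (1.45-fold) and APOBEC3H not (adjusted p = 0.621). Median centring left 5 and 5 higher, and quantile normalization 5 and 4. The 10 tested genes that flank the cluster had a median difference of 0.035 in the knockout against 0.479 for the family, on the deposited log2 scale, though 3 of the 10 were called. Reads of these paralogs can be divided between them.

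The tests of T cell markers below, the tests in left-out batches, the count of genes beyond wild type and its alternatives, the rule by which splits of 9 libraries were counted and the splits of the 9 within batches were chosen after results were seen.

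The 148 genes changed the same way in knockout and rescue were weighed first. A copy-number change carried by the edited line would move neighbouring genes too, but the 10 nearest tested genes moved with each gene by a median of 0.00804 (upper 95% bound 0.0148) in the rescue against wild type, where 0.3 had been set for such a change. A median over the 148 would not show a segment that holds a few of them. Gene by gene, the neighbours of 0 of the 148 moved with their gene by 0.3 or more. The highest was 0.224, at APOBEC3C and APOBEC3D. The 0.3 is on the deposited log2 scale, which understates changes of low genes, so a gain among such neighbours could stay under it. These values argue only against gains or losses that move many neighbouring genes by 0.3 or more on that scale. They do not argue against smaller segments or a change within 1 gene. Genes called so without a batch (60, 96 and 55 without batches 1, 2 and 3) kept their direction against wild type in the rescue of that batch in 98.3%, 97.9% and 100% of cases. This argues against noise of the shared wild-type libraries around a full return, for which simulations gave at most 1 such gene. The count of genes changed the same way was 90 without rescue replicate 3. A difference of the edited line that does not follow SOX11 stays open and untested for the 117 genes that had not been reversed. The other 31 had moved part of the way back in the rescue, so such a difference alone does not account for them.

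The 115 genes beyond wild type were weighed next, 96 of them lower in the knockout. Median centring or quantile normalization left at least 101, which argues against scaling between libraries. Of the 28, 61 and 12 genes called so without batches 1, 2 and 3, 100% kept their direction in the rescue of that batch, which argues against noise of the shared wild-type libraries around a full return, for which simulations gave 0 by limma. The count was 71 without wild-type replicate 3, and 65 and 56 without rescue replicates 2 and 3. SOX11 above its wild-type level, at 369.8%, is a candidate explanation that cannot be told apart from other features of the rescue line, since no line had SOX11 returned to the wild-type level.

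T cells were weighed for the rise of CD4, PRF1, CD3E and NKG7 in the knockout and of CD4, PRF1, CD3E and LCK in the rescue. In the knockout CD4 rose by 632, 709.7 and 657 normalized counts in batches 1, 2 and 3, while the summed counts of CD3D, TRAC, TRBC1 and TRBC2, abundant in T cells and at 8.22, 66.8 and 20.8 in wild type, changed by -3.32, -53.6 and -13.3, which argues against T cells among the knockout cells. A first test on all 7 receptor and CD3 chains had met neither bound set for it, with CD3G and CD247 at 376 and 749 in wild type. The sum of the 7 rose by 0.28 to 0.482 of the rise of CD4, above the share that the later tests took as a sign of T cells. The reading for the knockout thus depends on which chains are counted, and the fall of the 4 chains came mainly through TRAC. In the rescue the sum of the 4 chains rose by 21.9, 34.9 and 20.5, or 0.105 to 0.167 of the rise of CD4, which met neither bound. The rise came through TRAC (24.3 in wild type, 4.27 in the knockout and 52.6 in the rescue). CD3D, TRBC1 and TRBC2 without TRAC changed by -1.17, -5.12 and -1.37. TRAC was left out after its rise was seen, and the 3 chains left averaged 3.51, 1.03 and 3.07 in wild type. These values therefore do not decide on T cells among the rescue cells. A change in the Z138 cells themselves may be the source.

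Other splits of the libraries were counted for each result. For the 3 comparisons there are 10 splits of the 6 libraries, too few for a share under 0.05. As many genes were called in 1 of the 10 splits in each comparison, the real one, with 1470, 2556 and 470 genes, and the highest of the other splits was 0 each time, with up to 954, 614 and 1119 genes at an unadjusted p under 0.05. As many lists moved by camera in 1, 2 and 3 of the 10 splits, with 13, 8 and 12 for the real split and up to 11, 11 and 14 in the others. Among splits that part the 3 batches as the real one does, the others moved at most 8, 6 and 8 lists. For the reversed genes 1 of 100 splits of the 9 libraries gave as many as 1120, the real one, with 936 as the highest other. Of the 36 splits that keep 1 library of each batch in each group 1 gave as many (highest other 884). The 3 other splits that keep the knockout libraries together gave 831 to 884, and the highest of the remaining splits was 46. The count thus shows that the knockout libraries stand apart from the rest. It cannot exclude chance for the return in the rescue, since it is high wherever the knockout libraries are kept together. Each split was counted once, at the highest count over the ways to name its groups, after a first count had included renamed copies of the real grouping. Counted so, genes changed the same way in both repeat the reversed genes of another naming in each split (1120 for the real one, 936 for the highest other, and 1 of 100 as large), which says nothing about the 148, and chance is neither excluded nor shown for them. The highest other splits kept the 3 knockout libraries together, so the distance of the knockout from both other groups is a structure that such splits share.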
